A study of Mus musculus with 47 samples.

How the data were processed

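Chromatin of mouse liver was assayed by MNase-seq, in which micrococcal nuclease digests DNA that is not protected by nucleosomes and the protected fragments of about 1 nucleosome are sequenced. Per the labels, adult C57BL/6 mice were kept in 12 h light and 12 h dark, livers were taken from wild-type and Bmal1-/- mice at 6 zeitgeber times (ZT, hours after lights on), and nuclei were crosslinked with formaldehyde before digestion. BMAL1 and its partner CLK (CLOCK) form the transcription factor that drives the circadian clock. The submitters' processing notes name CASAVA 1.7, Bowtie and the mm9 genome build; the Bowtie version, the fragment length, the handling of duplicates and the target of the scaling are not given in the sources used here.

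The deposited table holds MNase signal, a scaled coverage, as the authors averaged it over sets of CLK:BMAL1 ChIP-seq peaks. Each of 47 libraries has a profile of 300 values, 10 bp apart, over a 3 kb window for each of 27 peak sets. A second deposited table lists 3217 peaks with mm9 positions and 1 genomic class each. The peak sets cover all peaks, 10 deciles of the list with 322 peaks each, 4 genomic classes with introns also given as a part of gene bodies, and smaller sets named as the top of these. The ranking behind the deciles is not given in the sources used here. The first decile lay within the set of the top 400 peaks, and the median ChIP-seq peak width was 399 bp in the first decile of the peak list and 229 bp in its last. The 4 classes, weighted by their numbers of peaks, gave the all-peak profile to within 0.000513 signal units. Gene body peaks outside introns were obtained by subtraction. Windows of 630 peaks (19.6%) overlapped that of another peak.

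Library depth was read from the smallest sets, where the signal of a library moves in whole multiples of 1 step, the worth of 1 covering fragment. With a tolerance of 0.1 of a step, 100% of the values were whole in every library, and the steps from the sets of 100 and 74 peaks differed by at most 0.00151%. Relative depth, with the shallowest library at 1, reached 2.09. About 23258 to 46736 fragments lay over a central position of the all-peak profile, a counting error of 0.463% to 0.656%. These counts cover counting error alone, and fragments without molecular identifiers need not be independent molecules.

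The tests had been planned for a signal value per peak. The deposited signal is averaged over peaks, so the planned limma contrasts (limma 3.58.1 in R 4.3.3, eBayes with a trend) were run over the 300 positions of the all-peak profile instead, on log2(signal + 5.51), where the pseudocount is the 10th percentile of the values. A log2 change on this scale understates the change of the signal itself. No further normalization was used. All 47 libraries entered 1 fit with 12 genotype by time groups, or a 24 h harmonic per genotype, and p-values were adjusted by Benjamini-Hochberg at 0.05. Neighbouring positions share fragments, so calls are given as the width in bp that they cover, at 10 bp per position, and not as a number of sites. The rule for named peaks (those of largest change among the peaks past the threshold, and every peak of core clock and clock output genes) and the tests of the gene lists need a value per peak and gene symbols, and were not run. The mm9 positions were not converted to the build of the reference genome.

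The mean log2 signal per mouse was tested between genotypes by an exact two-sided permutation test of the means of 4 wild-type and 4 Bmal1-/- replicate series, where a series is the mice that carry the same replicate number at the 6 times. The 70 assignments of 8 series allow no p below 0.0286. Light (ZT02, ZT06, ZT10) and dark (ZT14, ZT18, ZT22) were compared within a genotype by a two-sided permutation test of mice with 100000 resamples, whose smallest p is 1e-05. These designs, the alternatives for them and the pseudocount rule were fixed before the data were examined.

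A measure of the central trough was added after the data were seen, because the scaled level of whole windows differed between replicate series. The central signal is the mean within 150 bp of the window middle, close to the median ChIP-seq peak width of 309 bp. The flank signal is the mean beyond 1000 bp on both sides. Relative central signal is the central signal in percent of the flank signal, so differences are in percentage points. It was tested by the same exact and permutation tests, by exact tests of mice at each time, by a least-squares 24 h harmonic with times permuted over mice, and by exact tests of series differences for light against dark and for the harmonic between genotypes. Benjamini-Hochberg adjustment ran over 28 peak sets or 6 times. The sets overlap, and the exact tests of series allow no p below 0.0286. An adjusted p of these tests over the sets thus depends on how many sets reach that smallest p. Each library is 1 mouse per the labels, so p-values measure the spread between mice or between series.

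The limma step was tested on simulated data for the genotype effect over all times and for the 24 h rhythm in wild type. With 60 of 300 positions changed by 0.08 on the log2 scale in 20 runs, 100% were recovered in both comparisons, and 4.1% and 4.11% of the calls were false. Residuals were drawn independently for each position and library. In the data, neighbouring positions share fragments and libraries of a replicate series had a correlation of 0.726. The share of false calls in the data is therefore not given by these rates. The tests of relative central signal were tested on 100 simulated sets. A genotype difference of 8 percentage points was called in 100% of them and in 2% of sets without an effect. The wild-type harmonic was called in 100% and 5%. The simulated spread was the same in both genotypes and smaller than that of Bmal1-/- in the data. There the SD was 3.85 percentage points between series means and 5.41 between mice of a group, against 0.781 and 2.31 in wild type. The rates of the genotype test therefore do not cover the spread of Bmal1-/-. Alternatives were other pseudocounts, a filter on low positions, median centring, quantile normalization, limma without a trend, replicate numbers as a block, series means, time as a factor, each replicate left out in turn and, added later, flank scaling and other widths of the centre and flank. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.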

Results

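Nucleosome profiles around CLK:BMAL1 binding sites were measured by MNase-seq in livers of wild-type and Bmal1-/- mice, which lack the BMAL1 subunit of this factor. The 47 libraries were 24 from wild-type mice, 4 at each of 6 times of day, and 23 from Bmal1-/- mice, 4 at each time except ZT22 with 3. The sites were ChIP-seq peaks on 20 chromosomes (mm9). Of these, 1412 (43.9%) lay in introns, 6.56% elsewhere in gene bodies, 583 (18.1%) at transcription start sites (TSS), 9.14% intergenic within 10 kb of a gene and 717 (22.3%) intergenic beyond 10 kb, by the classes in the peak list. The first peak of the list lay at a TSS on chromosome 7, from 52960041 to 52960760. Relative depth was 1.52 ± 0.299 (SD, n = 24) in wild type and 1.36 ± 0.229 (SD, n = 23) in Bmal1-/- libraries, and the counting error of a central position was at most 0.656%. The deposited signal is an average over peaks, and single peaks and the targeted gene were not analysed here.

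The first comparison asked whether nucleosome signal at CLK:BMAL1 sites differs when BMAL1 is absent. Both genotypes had a trough of MNase signal at the sites, and the trough was shallower in Bmal1-/- livers. Over all peaks, relative central signal was 69.4% ± 0.781 of the flank in wild type (SD, n = 4 series) and 77.96% ± 3.85 in Bmal1-/- (SD, n = 4 series). The difference was 8.53 percentage points, and each Bmal1-/- series lay above each wild-type series (exact permutation p = 0.0286, the smallest possible). The series means were 70.2%, 68.4%, 69.8% and 69.4% in wild type and 79.6%, 77.2%, 73.05% and 82.1% in Bmal1-/-. In the first decile of the peak list the values were 65.5% ± 1.701 and 77.2% ± 5.15 (SD, n = 4 series each), a difference of 11.7 percentage points (exact permutation p = 0.0286). Without wild-type replicate 11, 12, 26 or 27 the exact p was 0.0571 in both sets (2 of 35 assignments), with differences of 8.17 to 8.78 over all peaks and 11.2 to 12.5 in the first decile.

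**Figure D1:**
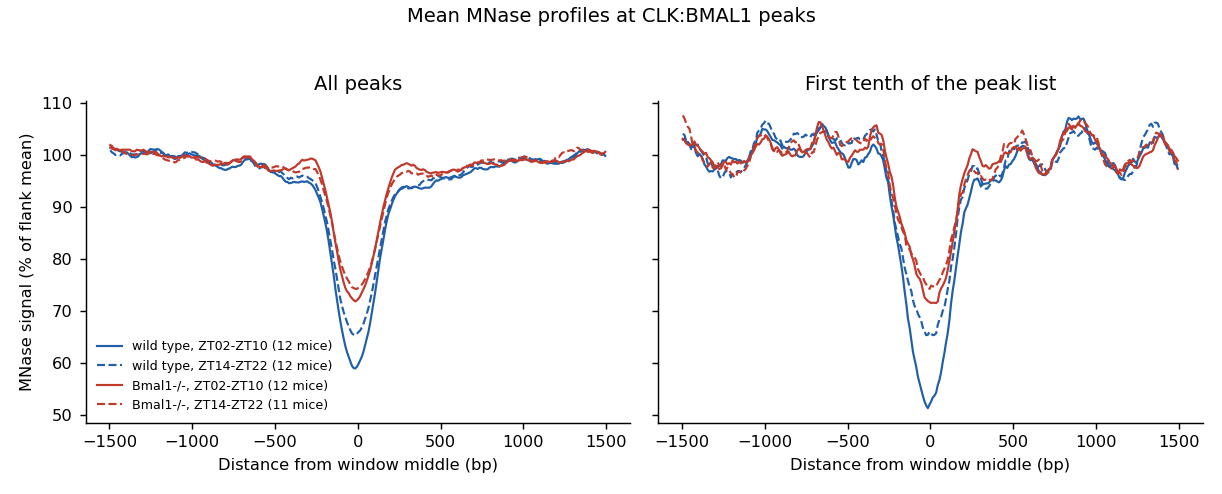
Mean MNase signal in percent of the flank mean (y axis) against the distance from the window middle in bp (x axis), for light and dark times in each genotype (12 mice per line, 11 for Bmal1-/- in the dark). The wild-type trough is the deeper one, and its relative central signal in the first decile is 60.3% in the light and 70.8% in the dark.

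As scaled by the authors, central signal was 4.72 ± 0.129 in wild type and 5.18 ± 0.362 in Bmal1-/- (SD, n = 4 series), a difference of 0.466 signal units that did not pass the test (exact permutation p = 0.114; without Bmal1-/- replicate 8 it was 0.643, p = 0.0286). Flank signal was 6.79 in wild type and 6.65 in Bmal1-/-, a difference of -0.147 (exact permutation p = 0.429). The mean log2 signal over the whole window differed by -0.0026 (exact permutation p = 0.886). By limma over the all-peak profile, 290 bp of the 3000 bp window were higher and 0 bp lower in Bmal1-/- at adjusted p under 0.05, and 270 bp of these lay within 150 bp of the middle. With each library centred on its median, 800 bp were higher and 290 bp lower, and with quantile normalization 370 and 150 bp. All of these fits take mice of 1 series as independent. With the means of the 8 series, limma called 0 bp (180 bp at an unadjusted p under 0.05). The calls moved to 720 bp higher without replicate 8, to 270 bp higher and 500 bp lower without replicate 27, and to 270 bp higher and 2100 bp lower without replicate 5.

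The second comparison followed the genotype difference over the day. Relative central signal over all peaks was higher in Bmal1-/- livers by 10.5 percentage points at ZT02, 12.0 at ZT06, 9.05 at ZT10 and 9.82 at ZT14 (exact permutation p = 0.0286 and adjusted p = 0.0429 at each of these 4 times). At ZT06 the values were 65.3% ± 1.77 in wild type and 77.3% ± 6.79 in Bmal1-/- (SD, n = 4 mice each; exact permutation p = 0.0286). At ZT18 they were 72.6% ± 1.76 and 76.2% ± 5.99 (SD, n = 4 mice each), which did not differ by more than the spread between mice (exact permutation p = 0.286). At ZT22 the difference was 8.14 percentage points with 4 and 3 mice (exact permutation p = 0.0571). The absent Bmal1-/- mouse was replicate 8, whose series lay nearest to wild type (73.05% over all peaks), so the ZT22 values leave that series out. Without Bmal1-/- replicate 5 the ZT22 difference was 4.63 (exact permutation p = 0.2). In the first decile of peaks, the difference was 14.3, 18.6, 15.95 and 10.8 percentage points from ZT02 to ZT14 (exact permutation p = 0.0286 and adjusted p = 0.0429 each), 1.86 at ZT18 (p = 0.514) and 12.0 at ZT22 (p = 0.0571). With the centre taken within 250 bp, the tests at ZT02, ZT06 and ZT14 over all peaks each gave exact p = 0.0571. With 1 mouse fewer, exact p = 0.0571 was also given at ZT02 and ZT06 without replicate 11, 12, 26 or 27 (9.87 to 11.4 and 11.3 to 12.7 percentage points), and at ZT14 without replicate 11, 12, 27, 9 or 10 (7.42 to 9.89). In the first decile it was given at ZT02 without replicate 11, 12, 26 or 27 (13.9 to 14.8) and at ZT14 without replicate 11, 12, 26, 27 or 9 (6.79 to 11.8). At ZT18 the test over all peaks passed without replicate 8 (6.21, exact p = 0.0286).

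On the scale of the authors, limma called a width of 110 bp around the middle at ZT06, from -55 to 45 bp, all of it higher in Bmal1-/-. At the other 5 times it called 0 bp (270, 230, 180, 50 and 20 bp at an unadjusted p under 0.05 at ZT02, ZT10, ZT14, ZT18 and ZT22). The width at ZT06 moved to 470 bp without replicate 8 and to 0 bp without replicate 12, 26, 27, 9 or 10. It was also 0 bp with 10 times the pseudocount, with quantile normalization and without the 25% of positions of lowest mean signal. Without replicate 8, limma called 700 bp at ZT02, 90 bp at ZT10 and 200 bp at ZT14 as higher in Bmal1-/-. Without replicate 5 it called 50 bp at ZT18 and 1440 bp at ZT22 as lower. With each library centred on its median, ZT02 had 190 bp higher and 140 bp lower, and ZT06, ZT10, ZT14 and ZT22 had 230, 210, 180 and 120 bp, all higher in Bmal1-/-. With quantile normalization, ZT02 had 150 bp, all lower in Bmal1-/-, and ZT22 had 20 bp higher. Without a trend in limma, ZT02 had 170 bp and ZT06 210 bp, all higher.

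**Figure D2:**
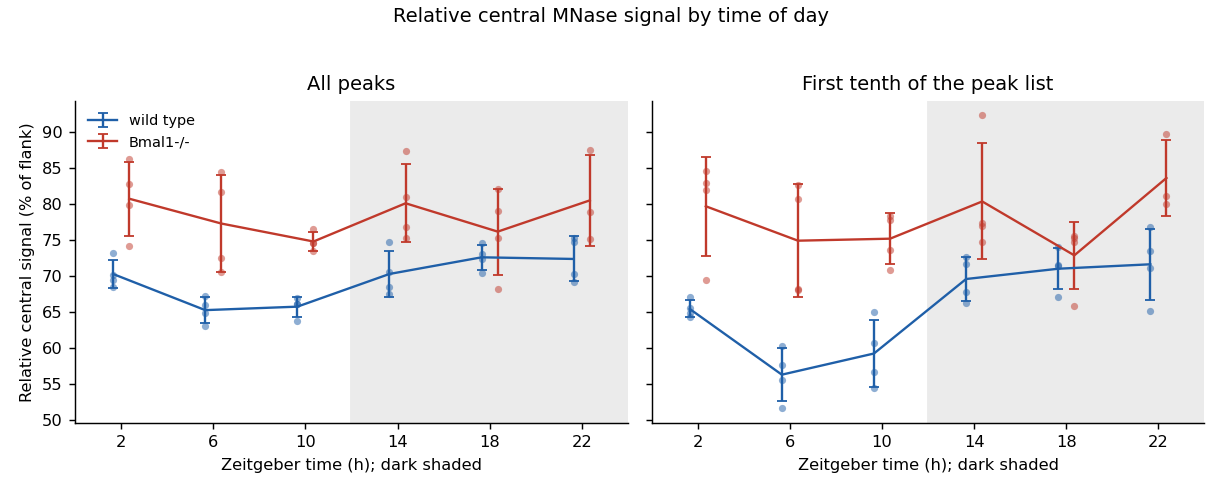
Relative central signal in percent of the flank (y axis) against zeitgeber time in h (x axis, dark shaded), with 1 point per mouse and lines with bars for the mean and SD of each group. Wild-type means in the first decile run from 56.3% at ZT06 to 71.6% at ZT22, and the genotypes are closest at ZT18.

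The third comparison asked whether nucleosome signal at the sites changes between light and dark and over 24 h. In wild-type livers the trough was deeper in the light. Relative central signal over all peaks was 67.1% ± 2.84 in the light and 71.8% ± 2.73 in the dark (SD, n = 12 mice each), a difference of -4.66 percentage points (permutation p = 0.00067), with the same sign in 4 of 4 series. In the first decile of peaks it was 60.3% ± 5.07 and 70.8% ± 3.48 (SD, n = 12 mice each), a difference of -10.4 percentage points (permutation p = 1e-05, the smallest possible). A 24 h harmonic had an amplitude of 4.03 ± 0.647 percentage points (SE, n = 24 mice) and a minimum at ZT 7.89 ± 0.613 h over all peaks (permutation p = 2e-05). In the first decile the amplitude was 8.02 ± 1.08 (SE, n = 24 mice) with the minimum at ZT 7.15 ± 0.515 h (permutation p = 1e-05).

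In Bmal1-/- livers no difference between light and dark was detected. Relative central signal over all peaks was 77.6% ± 5.17 in the light (SD, n = 12 mice) and 78.8% ± 5.65 in the dark (SD, n = 11 mice), a difference of -1.18 percentage points (permutation p = 0.604). The first decile gave -1.93 percentage points (permutation p = 0.501). The dark means over mice lack replicate 8 at ZT22, whose series was the lowest in Bmal1-/-. Of 4 Bmal1-/- series, 1 was lower in the light over all peaks and 3 were in the first decile. The 24 h amplitude was 1.85 ± 1.63 over all peaks (SE, n = 23 mice; permutation p = 0.529) and 2.07 ± 2.06 in the first decile (permutation p = 0.614). Light minus dark was compared between genotypes as the mean of the values of each series, and not as the mean over mice given above. The difference between genotypes in the light minus dark value was 9.17 percentage points in the first decile (exact permutation p = 0.0286). It did not pass adjustment over 28 sets (adjusted p = 0.0615, set by the 13 overlapping sets that share the smallest possible p). Over all peaks it was 4.01 and did not pass the test (exact permutation p = 0.0857), except without Bmal1-/- replicate 5 (5.25, p = 0.0286). The harmonics of the genotypes differed by 7.66 percentage points in the first decile (exact permutation p = 0.0286; 7.43 to 7.84 and p = 0.0571 without replicate 11, 12, 26 or 27) and by 3.59 over all peaks (exact permutation p = 0.143; 4.96 and p = 0.0286 without replicate 5).

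On the scale of the authors, limma called 0 bp of the window for light against dark in wild type (240 bp at an unadjusted p under 0.05), for the 24 h rhythm in wild type (270 bp at an unadjusted p under 0.05), and for both tests in Bmal1-/- and both differences between genotypes (0 bp at an unadjusted p under 0.05). With each library centred on its median, 130 bp were lower in the light in wild type and 150 bp had a rhythm, and without a trend in limma these were 130 and 210 bp. With quantile normalization limma called 0 bp for both in wild type (50 and 100 bp at an unadjusted p under 0.05) and a rhythm over 70 bp in Bmal1-/-. Without replicate 8 the wild-type widths were 220 and 290 bp, and without replicate 5 they were 80 and 70 bp. With the replicate numbers as a fixed block, 220 bp were lower in the light and 270 bp had a rhythm in wild type. In Bmal1-/-, 300 bp were then higher in the light. The light minus dark difference between genotypes then covered 1860 bp. The rhythm in Bmal1-/- and its difference between genotypes stayed at 0 bp. Mean log2 signal over the window changed between dark and light by -0.015 in wild type (permutation p = 0.0779; without replicate 27 it was -0.020, p = 0.0137) and by 0.0078 in Bmal1-/- (permutation p = 0.615). Averaged over series in place of mice, the light minus dark value differed between genotypes by 0.027 (exact permutation p = 0.0286). This difference gave exact p = 0.0571 without replicate 11, 26, 5, 8, 9 or 10 (0.023 to 0.030).

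The peaks were next taken by deciles of the list. Relative central signal was higher in Bmal1-/- in all 10 deciles, with exact permutation p = 0.0286 (adjusted p = 0.0348 over 28 sets) in 9 of them. The last decile had a difference of 5.81 percentage points (exact permutation p = 0.0857). The genotype difference fell by 0.523 percentage points per decile from the first decile to the last (exact permutation p = 0.0286), a trend with slopes from -0.585 to -0.422 and p = 0.0571 without replicate 27, 8, 9 or 10, -0.438 and p = 0.0857 without replicate 5, and -0.347 and p = 0.0857 with the centre taken within 250 bp. Light against dark in wild type passed the permutation test in 7 of 10 deciles, the first to the seventh, and in 0 of 10 deciles in Bmal1-/-. Light minus dark differed between genotypes by 9.17, 6.17 and 6.51 percentage points in deciles 1, 2 and 4 (exact permutation p = 0.0286 each). These did not pass adjustment over 28 sets (adjusted p = 0.0615 each). In the other deciles this exact p was 0.0571 to 0.914. Mice of a group varied more in Bmal1-/- over all peaks (SD 5.41 against 2.31 percentage points). The count of 0 deciles thus cannot show that Bmal1-/- lacks a change. In wild type the light minus dark difference was -6.27 in the second decile, -6.74 in the fifth, -3.82 in the seventh and -0.339 in the ninth (permutation p = 0.871), and its slope was 0.905 percentage points per decile (permutation p = 0.00013). The count of 9 deciles for genotype became 2, 1, 2 and 1 without wild-type replicates 11, 12, 26 and 27, where 3 series face 4. Exact p = 0.0286 can still be reached with 3 series against 4, so the number of series alone does not set these counts.

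**Figure D3:**
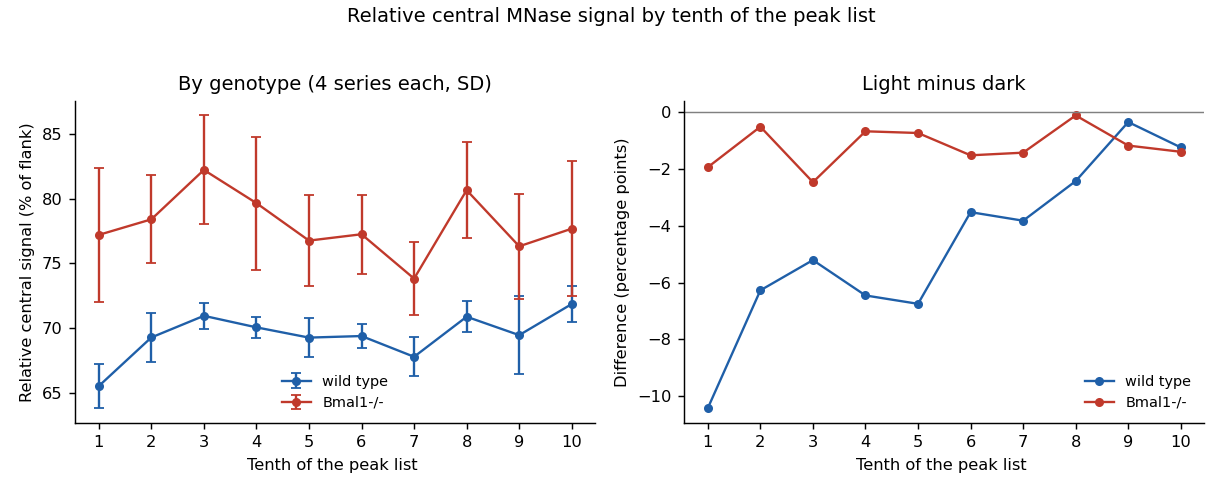
Left, relative central signal in percent of the flank (y axis) by decile of the peak list (x axis), as mean and SD of 4 series per genotype; right, the light minus dark difference in percentage points (y axis) per decile. The wild-type line on the right runs from -10.4 in the first decile to -1.23 in the last, while the Bmal1-/- values lie between -2.46 and -0.106.

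Genomic classes were compared in the same way. At intron peaks relative central signal was 71.4% ± 1.65 in wild type and 81.95% ± 3.75 in Bmal1-/- (SD, n = 4 series each), a difference of 10.5 percentage points (exact permutation p = 0.0286, adjusted p = 0.0348). The difference was 8.73 at other gene body peaks, 8 at intergenic peaks within 10 kb of a gene and 8.48 at those beyond 10 kb (exact permutation p = 0.0286 and adjusted p = 0.0348 each). Other gene body peaks gave exact p = 0.0571 with the centre taken within 50 or 250 bp or the flank beyond 750 bp. With 3 wild-type series against 4, exact p = 0.0571 was given at intron peaks without replicate 11, 12 or 27 (9.93 to 10.7), at other gene body peaks without any of the 4 (7.77 to 9.55), and at intergenic peaks within 10 kb without replicate 11 or 26 (7.73 to 7.92) and beyond 10 kb without replicate 12, 26 or 27 (8.28 to 8.42). At TSS peaks the trough was the deepest of the 5 classes in both genotypes, 58.8% ± 2.31 in wild type and 62.3% ± 5.41 in Bmal1-/- (SD, n = 4 series each), and the difference of 3.47 percentage points did not pass the test (exact permutation p = 0.257). It was 5.97 without replicate 8 and 1.80 without replicate 9 (exact permutation p = 0.0571 and 0.486). The genotype difference at intron peaks exceeded that at TSS peaks by 7.06 percentage points (exact permutation p = 0.0286). This call gave exact p = 0.0571 without replicate 5, 8, 9 or 10 (6.10 to 7.41) and p = 0.143 with the centre within 250 bp. Light minus dark in wild type was -4.94 at intron peaks, -6.93 at other gene body peaks, -6.08 and -3.97 at intergenic peaks within and beyond 10 kb, and -3.08 at TSS peaks (permutation p = 0.00202, 0.00085, 0.00195, 0.00853 and 0.0269). With the centre within 250 bp the p was 0.053 for intergenic peaks beyond 10 kb and 0.228 for TSS peaks, and TSS peaks gave -3.27, -2.17 and -2.34 without replicates 12, 26 and 27 (permutation p = 0.074, 0.163 and 0.156).

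**Figure D4:**
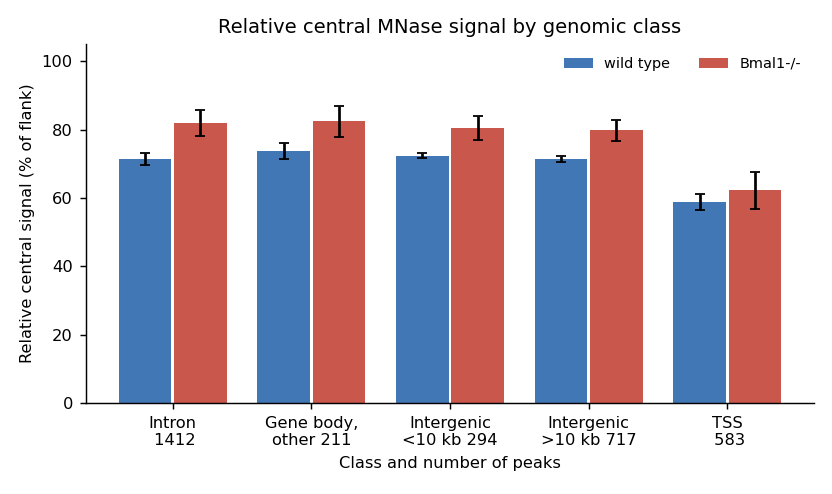
Relative central signal in percent of the flank (y axis, from 0) by genomic class (x axis, with numbers of peaks), as bars of the mean of 4 series per genotype with SD. The genotype difference runs from 3.47 percentage points at TSS peaks to 10.5 at intron peaks.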

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

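The tests of relative central signal, of handling and of a change shared by both genotypes were chosen after the data were seen; the depth tests of the light-dark difference were written before their results. Of 39 groups of 4 samples examined for a sample far from the others, 3 had one, where chance gives about 5%. At ZT14 in Bmal1-/-, replicate 9 had 92.3% relative central signal in the first decile of peaks and the nearest mouse 77.4%. At ZT18 in Bmal1-/-, replicate 8 had 65.9% and the nearest mouse 74.8%. At ZT18 in wild type, replicate 27 had a mean signal of 6.25 over all peaks and the nearest mouse 6.60. The light minus dark value differed between genotypes in mean log2 signal by 0.027 (exact permutation p = 0.0286).

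The light minus dark difference of relative central signal in the first decile of peaks differed between genotypes by 9.17 percentage points, and the harmonics by 7.66 (exact permutation p = 0.0286 for both). Of 28 peak sets, 13 gave such a difference in light minus dark at exact permutation p under 0.05, and 0 passed adjustment (smallest adjusted p = 0.0615). All 13 had the smallest possible p, so this adjusted p reflects their number and not the size of any difference. Library depth in the first decile was argued against, because with depth as a covariate the wild-type difference was -9.46 ± 1.78 percentage points (SE, n = 24) against -10.4 without it. Over all peaks it was -4.17 ± 1.17 against -4.66, which leaves open that depth took part, since 2 SE reach below 50% of the unadjusted size. Handling that differed by collection time and acted alike on all peaks was argued against by the slope of 0.9045 percentage points per decile, which held with each width of the centre. Handling that acted more on some peaks than on others could also give a slope, and was not tested. A change shared by both genotypes stays open, because the 9.174 of the first decile is the value that drew attention here and did not pass adjustment over sets, and the 4.005 over all peaks did not pass the test (exact permutation p = 0.0857). A clock-driven change of nucleosome signal at the leading peaks may be a candidate explanation, as a hypothesis that was found in these data and was not tested.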

How the results depend on the processing

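All tests of relative central signal, the central and flank signal, the flank scaling, and the exchange of mice or labels were chosen after the data were seen; the other alternatives had been planned. Of 337 values under alternatives that left out no replicate, 39 widths moved by more than 1.5 times, 14 tests fell below the threshold, 6 passed it and 0 reversed; the others kept their direction and their side of the threshold. With a replicate left out, 395 of 488 values were kept, 20 moved, 64 fell below the threshold, 5 passed it and 4 reversed. The cause was not tested unless stated.

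The widths called by limma moved with the scaling and other settings. With 10 times the pseudocount, ZT06 fell from 110 to 0 bp. Without the 25% of positions of lowest mean signal, which takes out the trough, the genotype effect over all times was 0 bp (380 bp at an unadjusted p under 0.05) and ZT06 0 bp. With each library centred on its median, the genotype effect was 1090 bp over all times (290 of them lower) and 330 at ZT02 (140 lower). At ZT06, ZT10, ZT14 and ZT22 it was 230, 210, 180 and 120 bp. Light against dark in wild type then covered 130 and its rhythm 150 bp. With quantile normalization the genotype effect was 520 bp over all times (150 of them lower), 150 (all lower) at ZT02, 0 at ZT06 and 20 at ZT22. A rhythm in Bmal1-/- then covered 70 bp. Without a trend in limma, ZT02 had 170, ZT06 210, light against dark in wild type 130 and its rhythm 210 bp. With the means of the 8 series the genotype effect was 0 bp. Relative to the flank mean, the genotype effect was 900 bp over all times, 250 at ZT02 (70 of them lower), 230 at ZT06, 170 at ZT10 and 160 at ZT14. Light against dark in wild type then covered 120 and its rhythm 150 bp.

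Replicate numbers recur at the 6 times, and a block was tried for them. In 79.1% of the pairs of libraries with the same number, profiles centred on their group mean correlated above 0.1 (median 0.331, lowest -0.645). For other numbers of the same genotype it was 30.2% of the pairs, with a median of -0.215, so profiles were partly shared by number. The numbers were still not taken as pairing, because some pairs of the same number did not correlate. Only 15 of 47 libraries correlated best with their own number. Leaving the numbers out of the main tests is thus a choice, and not a sign that they carry nothing. The correlation of profiles leaves out the level of a whole window. That level differed between numbers in Bmal1-/- (permutation p = 1e-05) and in wild type (permutation p = 0.00236). The check thus does not bear on a block in level. For light against dark, limma without a block counts those differences as spread between mice. For genotype, each series lies within 1 genotype. There, limma without a block takes mice of 1 number as independent, and its p-values over all times can be too small. With the numbers as a random block (correlation 0.726) limma called 0 bp for the genotype effect over all times and at ZT06. With flank scaling as well, it called 520 bp over all times, 220 at ZT02 (40 of them lower), 240 at ZT06, 190 at ZT10 and 180 at ZT14. As a fixed block the numbers gave 220 bp for light against dark in wild type, 300 bp in Bmal1-/-, 1860 bp for the difference and 270 bp for the wild-type rhythm. With labels exchanged within a number, mean log2 signal in light minus dark in wild type was -0.015 (permutation p = 0.0191). With mice exchanged between genotypes in place of series, central signal differed by 0.489 (permutation p = 6e-05), flank signal by -0.135 (permutation p = 0.049) and relative central signal at TSS peaks by 3.799 (permutation p = 0.0163), where mice of 1 number are taken as independent.

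Other choices moved single tests. The genotype difference in the light minus dark value of mean log2 signal was 0.022 with the median over positions and 0.021 without the lowest positions (exact permutation p = 0.0571 for both). With the centre within 250 bp, the slope over deciles was -0.347 (exact permutation p = 0.0857) and intron minus TSS 5.66 (p = 0.143). The same width gave 8.63 at ZT02, 9.66 at ZT06 and 7.87 at ZT14 over all peaks, 7.09 at other gene body peaks (exact permutation p = 0.0571 each), and 9.68 at ZT02, 7.56 at ZT14 and 8.26 at ZT22 in the first decile (p = 0.0857, 0.143 and 0.0286). It also gave light minus dark in wild type of -2.50 beyond 10 kb and -1.84 at TSS peaks (permutation p = 0.053 and 0.228). Other gene body peaks gave 10.04 with the centre within 50 bp and 8.65 with the flank beyond 750 bp (exact permutation p = 0.0571 for both), and ZT22 over all peaks gave 8.14 with that flank (p = 0.0286).

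Leaving out each replicate number in turn gave these ranges. By limma, the genotype effect covered 210 to 2370 bp over all times, 0 to 700 at ZT02, 0 to 470 at ZT06, 0 to 90 at ZT10, 0 to 200 at ZT14, 0 to 50 at ZT18 and 0 to 1440 bp at ZT22. Light against dark in wild type covered 0 to 220 bp and its rhythm 0 to 290 bp. Over all times, lower calls came to outweigh the higher ones without replicate 27 (770 bp, of them 500 lower) and replicate 5 (2370 bp, of them 2100 lower), while 270 bp higher were called in both. Mean log2 signal differed between genotypes by -0.017 to 0.013, with the sign reversed without replicate 11 (0.0036) and replicate 8 (0.013); in light minus dark it was -0.020 to -0.011 in wild type, with 0.023 to 0.032 as the difference between genotypes. Central signal differed by 0.382 to 0.643.

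Relative central signal differed between genotypes by 7.16 to 10.2 percentage points over all peaks and 10.1 to 14.1 in the first decile. By time it differed over all peaks by 8.62 to 12.7 at ZT02, 9.65 to 14.3 at ZT06, 7.42 to 11.4 at ZT14, 1.59 to 6.21 at ZT18 and 4.63 to 10.8 at ZT22, and in the first decile by 12.6 to 17.7 at ZT02 and 6.79 to 12.7 at ZT14. By class the ranges were 9.15 to 12.1 at intron peaks, 7.55 to 10.6 at other gene body peaks, 6.37 to 9.14 and 7.34 to 9.74 at intergenic peaks within and beyond 10 kb, 1.80 to 5.97 at TSS peaks, and 5.77 to 8.30 for intron minus TSS. The slope over deciles was -0.611 to -0.422, and 1 to 10 deciles passed. Light minus dark in wild type was -4.55 to -2.17 at TSS peaks, and its difference between genotypes over all peaks 3.49 to 5.25. In Bmal1-/-, light minus dark was -1.66 to -0.0764 over all peaks and -2.85 to -1.19 in the first decile, and the 24 h amplitude 0.754 to 2.41 and 0.592 to 3.55. The harmonics differed by 2.98 to 4.96 over all peaks and 7.23 to 9.03 in the first decile. Most calls that ended did so without a wild-type series at exact p = 0.0571, where 2 of 35 assignments gave a difference as large.

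Alternatives planned for named peaks and gene lists were not run, because the signal used here is averaged over peaks. Depth limits a central position over all peaks to a counting error of at most 0.656%, which covers counting error alone.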

Other observations

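The tests in this part were chosen after the data were seen. For the splits of libraries scaled to the flank, the rule for reading them was written before their results. The lowest point of the smoothed trough over all peaks was 62.5% ± 2.17 of the flank in wild type and 72.9% ± 3.99 in Bmal1-/- (SD, n = 4 series each; exact permutation p = 0.0286). Its width at mid depth was 302.1 ± 39.99 bp and 298.2 ± 51.85 bp (SD, n = 4 series each; exact permutation p = 1), so a change in depth was detected and a change in width was not. From 200 to 400 bp on both sides, signal was 93.8% and 97.1% of the flank (exact permutation p = 0.229). In wild type the lowest point was 59.3% ± 3.84 in the light and 65.6% ± 3.18 in the dark (SD, n = 12 mice each; permutation p = 0.00028), and 51.5% and 64.8% in the first decile of peaks (permutation p = 2e-05). Mice of 1 group and time varied more in Bmal1-/- than in wild type, with residual SDs of relative central signal of 5.41 and 2.31 percentage points; this difference was not tested.

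The higher relative central signal in Bmal1-/- was weighed against depth and digestion. With relative depth as a covariate the genotype difference was 7.80 ± 1.31 percentage points over 47 libraries, against 8.75 ± 1.32 without it (SE). These 2 SE take mice of 1 series as independent. Over the 8 series means the genotype difference was 7.68 ± 2.00 (SE) with the covariate, against 8.53 without it. Depth did not carry all of it, but 2 SE over the series reach below 50% of that size, so a large part stays open. A difference in digestion that acts alike on all peaks would give no slope over deciles, and the slope was -0.523 ± 0.167 (SE, n = 8 series; exact permutation p = 0.0286), but -0.347 ± 0.149 with the centre within 250 bp (p = 0.0857). A difference in digestion that grows with how open a site is was predicted to be largest at TSS peaks. Intron peaks exceeded them by 8.32 ± 1.24 percentage points with the centre within 50 bp and by 7.061 ± 1.99 within 150 bp (SE, n = 8 series; exact permutation p = 0.0286 for both). Within 250 bp the excess was 5.66 ± 2.90 (exact permutation p = 0.143), of the same sign with a wider spread between series. At the narrower centres the values thus went against digestion that acts alike on all peaks, and the spread at the widest keeps it open. Digestion that grows with how open a site is also stays open. TSS peaks had the deepest trough in both genotypes and may have less signal left to change, so their smaller difference cannot decide. Genotype itself, which the design names, stays among the open explanations, as untested.

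Signal over the whole window differed between replicate numbers, from 6.02 in Bmal1-/- replicate 8 to 6.77 in Bmal1-/- replicate 5, with 6.26 to 6.58 in the wild-type series. Over the 8 series means, mean signal and relative depth gave Pearson r = -0.513 (exact permutation p = 0.213, adjusted 0.426) and Spearman rho = -0.071 (exact permutation p = 0.882, adjusted 0.882), with r = -0.495 without the 2 series farthest from the median depth. The interval of r from -0.894 to 0.300 leaves depth open. Genotype alone was argued against as the source of these differences, because series of 1 genotype differed from each other. They differed by up to 0.749 signal units in Bmal1-/- (permutation p = 1e-05, the smallest that 100000 resamples can give). In wild type they differed by up to 0.325 (permutation p = 0.00236). Both tests exchanged numbers among the mice of each time. The mean of the genotypes differed by -0.0273 (95% interval -0.437 to 0.382, exact permutation p = 0.857). This interval leaves a further shift of level with genotype open.

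Other splits of the same libraries bear on the limma counts. Of 35 splits of the 8 series, 15 gave at least the 290 bp of the genotype effect over all times, and another split gave 3000 bp, so chance could not be excluded. That split set Bmal1-/- replicates 10 and 8 and wild-type replicates 12 and 27 against the rest, which points to a structure of the samples in overall level. At ZT06, 1 of 35 splits, the real one, gave 110 bp (highest other 100 bp), which excludes chance at 0.05 for this time taken alone, by 10 bp and with no allowance for the 6 times tested. The call was 0 bp with 10 times the pseudocount and with quantile normalization. For the other 5 times and both differences between genotypes, limma called 0 bp, which 35 of 35 splits meet by construction, so the splits say nothing about chance there. The highest other splits gave 50, 0, 1440, 1030 and 0 bp at ZT02, ZT10, ZT14, ZT18 and ZT22, where those of ZT14 and ZT18 point to a structure of the samples, and 0 bp for both differences. For light against dark and the rhythm, the 0 bp called is likewise met by 100 of 100 splits by construction. The highest other split gave 0 bp in wild type and 3000 bp in Bmal1-/-. The latter points to a structure of the samples, and whether it is the same one was not examined. With each library relative to its flank mean, 4 of 35 splits gave at least the 900 bp of the genotype effect (highest other 1310 bp), so chance could not be excluded there. In wild type, 1 of 100 splits gave 120 bp for light against dark (highest other 0 bp) and 1 of 100 gave 150 bp for the rhythm (highest other 60 bp), which excludes chance at 0.05. This scaling was chosen after the data were seen, and on the scale of the authors limma called 0 bp for both.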
